A study of Saccharomyces cerevisiae with 11 samples.

How the data were processed

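Replicating DNA of budding yeast (Saccharomyces cerevisiae) was measured by density transfer in a strain with 35 copies and a strain with 180 copies of the ribosomal DNA repeat. Cells grown with heavy isotopes were arrested in G1 with the mating pheromone alpha factor, moved to light medium and released into S phase with Pronase. DNA was cut with EcoRI and separated in caesium chloride gradients into unreplicated heavy-heavy (HH) and replicated heavy-light (HL) DNA. HH DNA was labelled with Cy3 and HL DNA with Cy5, and both were hybridized to the same Agilent tiling array. The 35 rDNA strain was sampled at 30, 35, 40, 45 and 50 min, the 180 rDNA strain at 25, 30, 35, 40, 45 and 55 min. Each time is 1 array, and the labels give 1 time course per strain. The replicate numbers 1 to 5 and 1 to 6 therefore stand for times, and an error over arrays is a spread over times, not between cultures.

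The deposited scanner files hold, per the file headers, an intensity for each channel from Feature Extraction, with the background subtracted, a spatial trend removed and 1 linear dye factor per channel. The median pixel brightness of each spot and of its local background is given there in the same unit, intensity, without normalization. The deposited value table holds a score per probe that stands for the percent replicated. It was checked against the scanner files: each column equals the red over green ratio of its array, scaled by a factor per array and carried to a share with a ceiling of about 110 (35 rDNA arrays) or 109 (180 rDNA arrays), with a largest deviation of 0.00521 points. Some of its values are therefore above 100. According to the authors, slot blots set the level of each array, and a correction was made for cells that did not complete S phase. The slot blot values themselves and the number of times each gradient was run are not given in the sources used here.

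Each array holds 41458 nuclear probes with a median spacing of 257 bp in sacCer2 coordinates, 295 mitochondrial probes and 22 probes without coordinates, which were left out. Arrays have no counts. Between 33 and 534 nuclear probes per array were not well above background, except for 4122 on the 25 min array of the 180 rDNA strain. The number of arrays limits the precision. The arrays come from 4 slides in 3 scans. No slide or scan holds both strains. The Feature Extraction protocol in the file headers also differs, a ChIP protocol for the 35 rDNA arrays and a CGH protocol for the 180 rDNA arrays. The processed signals of the strains were thus made under different protocols. Strain and batch cannot be told apart, and no value within a batch can be given.

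The log2 of HL over HH was averaged over the probes of 5 kb windows with at least 5 probes, giving 2324 windows. Each array was centred on its median window and scaled to a common median absolute deviation, so the values describe relative replication time. The 8 arrays of the 4 shared times (30, 35, 40 and 45 min) were fitted in limma with strain and time as factors, and p-values (2-sided) were adjusted by Benjamini-Hochberg over windows with a threshold of 0.05. The same fit was run with each 35 rDNA array paired with the 180 rDNA array taken 10 min earlier, an alternative chosen after the genome means of the value table were seen. Positive differences mean relatively earlier replication in the 35 rDNA strain.

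Region lists were fixed before the data were examined: windows within 20 kb of a centromere, within 30 kb of a chromosome end, 50 kb on either side of the rDNA, the rest of the right arm of chromosome XII, each chromosome, and windows that hold histone genes, ribosomal protein genes, tRNA genes, Ty gag-pol genes, COS genes, PAU genes, the silent mating loci, ASP3 genes, origin firing factor genes, rDNA and mitotic exit genes, or replication licensing genes. The ASP3 genes lie in 0 tested windows. Lists of replication origins and of long terminal repeats were dropped, because the annotation holds none. Genes were placed with R64 positions on the sacCer2 windows. As a check, the bodies of 26 Ty gag-pol genes held 2 probes at their R64 positions and 251 when moved by 3000 bp to the left. The median difference of a list, less the median of all windows, was compared with all 2324 rotations of the list along the genome and with 10000 random lists matched on mean replication time, each as a 2-sided permutation p adjusted over 31 lists. Calls rest on the rotations, which keep the clustering of a list. On simulated data without a planted difference, the windows right of the rDNA passed an unadjusted 0.05 in 3 of 50 simulations with rotations and in 17 of 50 with matched lists. Planted differences of 1.0 on the log2 scale in 200 windows were recovered for 78.5% of windows at equal times and for 97.5% with the arrays 10 min apart, and planted differences of 0.5 for 0% and 76.0%.

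Windows were named by a rule fixed before the data were examined. Neighbouring windows past the threshold with the same sign in all 4 pairs were merged into runs, and the 10 runs with the largest and the 10 with the lowest peak difference were named. Where fewer passed, the remaining places went to the windows with the largest differences of 1 sign in all pairs, given as values only. The genes of the fixed lists could be named, and so could the 5 highest peaks and 5 lowest valleys of a loess profile (22 kb, steps of 500 bp) in each strain. Peaks stood at least 0.25 scaled units above the lower flanking minimum and were shared if within 5 kb. Positions with fewer than 5 probes within 2.5 kb were left out of the named peaks, a choice made after they were seen.

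The 4 probes in the spacer of the rDNA repeat were averaged per array, and the arrays of the strains (5 against 6) were compared by exact permutation tests (2-sided, 462 splits). A probe counted as having lost its signal when its mean total signal lay over 3 log2 units under the array median. Percentages at equal genome means were interpolated on the log2 odds scale. Alternatives to these choices covered centring without scaling, percentiles, quantile normalization, normexp with an offset of 50, loess within arrays, no background subtraction, probe filters, windows of 2 and 10 kb, the loess profile, a quadratic in time, other time pairings, the deposited percentages, slide as a random block, and leaving out each pair or array. Background corrections were run on median spot signals, because the files hold no mean signals. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.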

Results

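Replication of the yeast genome was followed through 1 S phase in each of the strains, with 5 arrays for the 35 rDNA strain and 6 arrays for the 180 rDNA strain. The ribosomal DNA (rDNA) is a tandem array of repeats on chromosome XII that encode the ribosomal RNAs, and each repeat holds a potential replication origin. The labels give 35 copies for one strain and 180 for the other. Each array compared replicated with unreplicated DNA of 1 sample at 41458 nuclear probes. No slide holds both strains, so every difference between the strains below is also a difference between slides and between Feature Extraction protocols.

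The first question was how fast the genome as a whole replicated. The genome of the 35 rDNA strain reached each level of replication later after release than that of the 180 rDNA strain. Its mean percent replicated was 3.62% at 30 min, 8.64% at 35 min, 29.4% at 40 min, 48.3% at 45 min and 68.3% at 50 min. In the 180 rDNA strain it was 3.1% at 25 min, 18.7% at 30 min, 44.8% at 35 min, 65.0% at 40 min, 73.8% at 45 min and 90.1% at 55 min. A genome mean of 10% was reached 8.11 min later in the 35 rDNA strain and a mean of 60% was reached 9.15 min later, with 7.48 to 9.13 min at the levels in between. Windows reached 50% of their final value at a median of 41.6 min in the 35 rDNA strain and 34.9 min in the 180 rDNA strain. All 2324 windows were later in the 35 rDNA strain, by a median of 6.38 ± 0.950 min (SD over windows). The final time differs between the courses, and with a fixed level of 40% the median difference was 8.69 ± 1.14 min over 2315 windows. The order of the windows was similar in both strains, with a Spearman correlation of the times of 0.917 across windows, which are not independent replicates. With 1 time course per strain, this difference has no test against the spread between cultures.

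The rDNA replicated ahead of the genome mean in the 35 rDNA strain and behind it in the 180 rDNA strain for most of S phase. This comparison addresses when the repeats replicate in relation to the rest of the genome. In the 35 rDNA strain the 4 spacer probes of the repeat, on chromosome XII from 459765 to 460588 (sacCer2) between the large rRNA genes, were replicated to 15.2 ± 1.69% at 30 min, 26.2 ± 3.81% at 35 min and 56.9 ± 3.86% at 40 min (SD over 4 probes). This was 11.6, 17.5 and 27.5 points above the genome mean of the same arrays. The rDNA of the 180 rDNA strain was at 8.97 ± 1.73% at 30 min and 33.6 ± 4.75% at 35 min, and its distance to the genome mean was -9.70 and -11.2 points. The distance of the mean was -0.340 points at 50 min in the 35 rDNA strain and 1.28 points at 55 min in the 180 rDNA strain. The first of these values rests on the probe that overlaps the 5S rRNA gene, which was at 50.9%, while the other 3 were at 73.0% to 74.3% and so above the genome mean of 68.3%.

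On the clock the rDNA of both strains reached the 40% level at similar times. This was at 37.3 min in the 35 rDNA strain and at 36.2 min in the 180 rDNA strain, while the genome mean reached 40% at 42.8 and 34.1 min. Other times differed more. The rDNA of the 35 and 180 rDNA strains was at 15.2% and 8.97% at 30 min and at 26.2% and 33.6% at 35 min. It was at 56.9% and 60.8% at 40 min, and at 63.8 ± 9.32% and 71.2 ± 5.83% at 45 min (SD over 4 probes). At an equal genome mean of 20%, the rDNA was replicated to 45.4 ± 4.10% in the 35 rDNA strain and to 9.93 ± 1.89% in the 180 rDNA strain. The difference was 39.0 ± 4.32 points at a genome mean of 30%, 32.8 ± 7.76 points at 40% and 12.5 ± 12.3 points at 60%. Relative to the array median, log2 of HL over HH at the spacer probes averaged 1.51 ± 1.16 (SD, n = 5) and -0.37 ± 0.42 (SD, n = 6), a difference of 1.87 with an exact permutation p of 0.00433. With normexp background correction the difference was 1.10 with an exact permutation p of 0.338, so the call depends on the background correction. Both p-values take successive times of 1 course per strain as independent arrays. In the 35 rDNA strain the value without normexp fell from 2.86 at 30 min to -0.06 at 50 min.

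**Figure D1:**
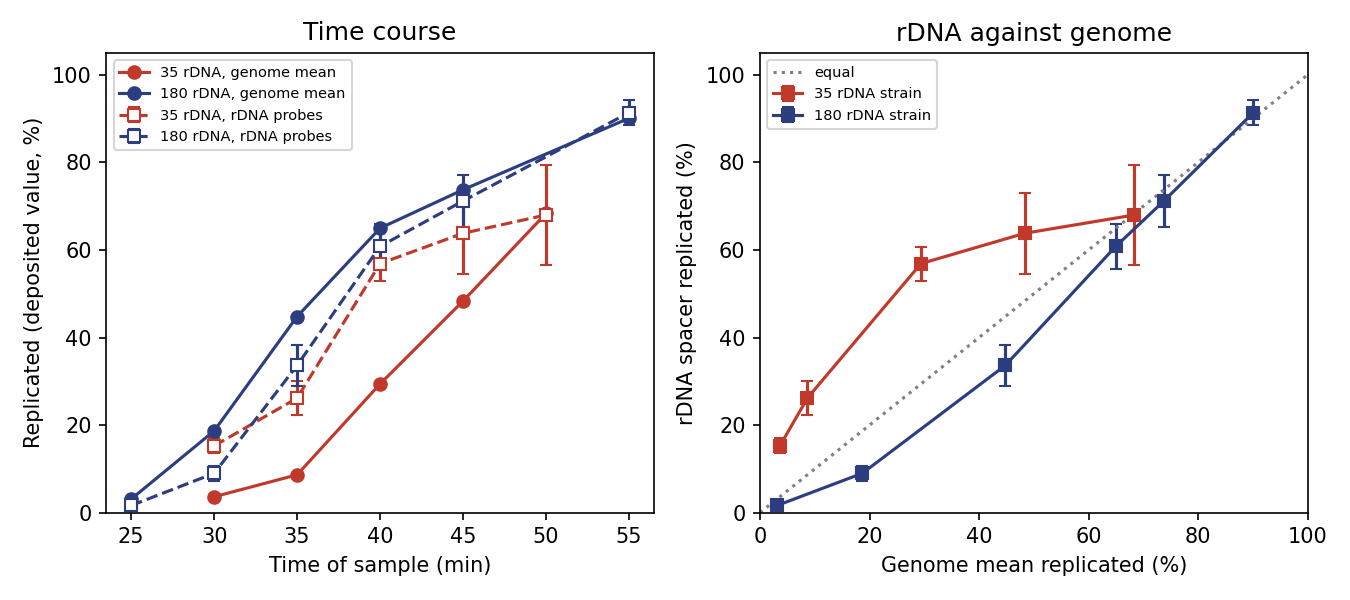
Percent replicated of the genome mean and of the 4 rDNA spacer probes (mean and SD over probes) against time in min, and the rDNA percent against the genome mean percent, with 1 point per array. The rDNA of the 35 rDNA strain lies above the line of equality up to a genome mean of 48.3%, and that of the 180 rDNA strain lies below it from 3.1% to 73.8%.

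The signal of the spacer probes was also compared, since the labels give a 5.14-fold difference in copies. In unreplicated DNA the mean of the 4 spacer probes was lower in the 35 rDNA strain, with a log2 difference of -1.20 or a 2.30-fold higher signal in the 180 rDNA strain (exact permutation p = 0.00216, the smallest that 462 splits can give). The HH levels over the array median were 3.70 ± 0.38 (SD, n = 5) and 4.90 ± 0.34 (SD, n = 6). The probe that overlaps the 5S rRNA gene went the other way, with HH levels of 4.22 to 5.82 in the 35 rDNA strain and 3.35 to 4.29 in the 180 rDNA strain. In replicated DNA the difference was 0.65 (exact permutation p = 0.123), and averaged over both channels it was -0.28 (exact permutation p = 0.171). Corrected for the unreplicated share, the copy estimate was 1.77-fold higher in the 180 rDNA strain. Without this probe it was 2.82-fold higher, and the HH signal was 3.87-fold higher, both at the smallest p of 0.00216 in the exact permutation test. Both choices were made after the data were seen. These permutation tests also take successive times of 1 course per strain as independent arrays.

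A few genes had no signal in 1 or both strains. All 7 probes of FOB1, which encodes the replication fork barrier protein of the rDNA, lay far under the array median in both strains, with a mean log2 signal of -5.73 ± 0.25 (SD, n = 5) in the 35 rDNA strain and -6.03 ± 0.57 (SD, n = 6) in the 180 rDNA strain. The 4 probes of LEU2, a leucine biosynthesis gene, and the 3 probes of MET17, a sulfur assimilation gene, had lost their signal in the 35 rDNA strain only, at -5.75 ± 0.19 and -6.53 ± 0.13 (SD, n = 5), against 0.32 ± 0.27 and -0.28 ± 0.44 (SD, n = 6). These 3 were the genes with lost signal among 4093 genes scanned, a scan made after the data were seen. The strains thus differed at LEU2 and MET17 as well as in the labelled rDNA copies.

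Within each strain, each list was also compared with the rest of the genome. Windows near centromeres were replicated earlier than the other windows on all 11 arrays, by a mean log2 of 1.25 (range 0.62 to 1.74, n = 5) in the 35 rDNA strain and 1.12 (range 0.44 to 2.51, n = 6) in the 180 rDNA strain, in the top 2.5% of rotated lists on each array. Windows near chromosome ends lay below the rest on all 11 arrays, with means of -0.33 and -0.39, and were in the lowest 2.5% on 2 of 5 and 4 of 6 arrays. Windows with tRNA genes lay above the rest on all arrays, by 0.58 and 0.56, and in the top 2.5% on each. Windows with histone genes had mean differences of 1.51 and 1.06 and were in the top 2.5% on 4 of 5 and 2 of 6 arrays. The windows left of the rDNA had means of 1.02 in the 35 rDNA strain and 0.66 in the 180 rDNA strain, and those right of it had 0.74 and 0.44, with 0 of 11 arrays in the top 2.5%. Windows with ribosomal protein genes had 0.17 and 0.24, in the top 2.5% on 1 of 5 and 5 of 6 arrays. Chromosome XIV had -0.39 and -0.46, in the lowest 2.5% on 2 of 5 and 5 of 6 arrays, and chromosome IV -0.32 and -0.33, on 3 of 5 and 3 of 6.

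Named early peaks of the smoothed profile in the 35 rDNA strain lay at ECM9 on chromosome XI (449000, scaled log2 of 1.99), between UTP20 and the histone gene HTA2 on chromosome II (232000, 1.98), and at PRM6 and PRP39 on chromosome XIII (181500, 1.94). Further peaks lay near HOG1 on chromosome XII (373000, 1.91) and near CCT8 on chromosome X (418000, 1.87). In the 180 rDNA strain the highest were beside CDC10, a septin gene close to the centromere of chromosome III (116000, 1.80), beside UTP20 (230500 on chromosome II, 1.69), beside WBP1 on chromosome V (151000, 1.69), beside GCN20 on chromosome VI (162500, 1.5) and at PRM6 (181500 on chromosome XIII, 1.47). The lowest valley of both strains lay at RDS1 and AAD3 near the right end of chromosome III, at -2.26 in the 35 rDNA strain and -3.11 in the 180 rDNA strain. YTA7 and SLH1 on chromosome VII lay in another valley of both strains, at -1.85 and -2.23. The other valleys of the 35 rDNA strain were at DUN1 (-1.85) and THI13 (-1.80) on chromosome IV and at AMA1 on chromosome VII (-1.76). Those of the 180 rDNA strain were at RVB1 (-2.53) and PAM1 (-2.21) on chromosome IV and at MRE11 on chromosome XIII (-2.27).

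The profiles of the strains were compared to see how far the order of replication was shared. The smoothed profiles held 326 peaks in the 35 rDNA strain and 349 in the 180 rDNA strain, and 231 of the 326 lay within 5 kb of a peak of the other strain. Rotated profiles shared 94.5 on average and at most 127 in 1000 rotations. Over windows, which are not independent replicates, the mean Spearman correlation between strains was 0.843 at equal times (0.699 at 30 min to 0.924 at 45 min) and 0.953 when the 180 rDNA array was taken 10 min earlier. Neighbouring times within a strain correlated at 0.952 and 0.944. Peak numbers rested on the smoothing, with 731 and 802 peaks at a span of 10 kb.

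The strain comparison by window asked which parts of the genome replicated relatively earlier or later once the level of each array was removed. The left end of chromosome VIII had the largest difference toward earlier replication in the 35 rDNA strain at equal times. The window from 5001 to 10000, with the subtelomeric gene COS8 and the siderophore transporter gene ARN2, differed by 2.06 ± 0.18 (SE, 4 pairs), followed on the same arm by the window of PAU13 (1.59 ± 0.17) and that of ARN1 (1.36 ± 0.12). Other high values were 1.61 ± 0.23 at RFX1 and TFS1 (chromosome XII, 510001 to 515000), 1.48 ± 0.15 at PYK2 and PUT4 (chromosome XV) and 1.32 ± 0.25 at BUL1 (chromosome XIII). Then came 1.11 ± 0.21 at UME6 (chromosome IV), 1.07 ± 0.28 at CDC42 (chromosome XII), and 1.06 ± 0.32 and 1.04 ± 0.37 at AAD3 and PAU3 (chromosome III). The AAD3 and PAU3 windows were replicated to only 3.26% against 2.66% and 8.50% against 7.04% at a genome mean of 30% (35 against 180 rDNA strain). Their mean difference at equal genome means was 1.73 and 1.58 points. The lowest were -0.75 ± 0.13 at SSN8 (chromosome XIV), -0.73 ± 0.16 at BPT1 (chromosome XII), -0.71 ± 0.17 at SPB4 (chromosome VI), -0.71 ± 0.17 and -0.70 ± 0.16 at MIA40 and CNB1 (chromosome XI), -0.68 ± 0.18 at SWI4 (chromosome V), -0.68 ± 0.23 at YAP5 (chromosome IX), -0.66 ± 0.14 at ESP1 (chromosome VII), and -0.64 ± 0.13 and -0.63 ± 0.16 at FKS1 and EST2 (chromosome XII). None of these windows passed: in limma 0 of 2324 windows were past the adjusted threshold (smallest adjusted p 0.0577), while 521 had an unadjusted p under 0.05. The sign was the same in all 4 pairs for 799 windows or 34.4%, where independent signs would give 12.5%. With slide as a random block 0 windows passed and 3 had an unadjusted p under 0.05, but no slide holds both strains, so this fit cannot separate strain from slide. A quadratic in time over all 11 arrays passed 423 windows (281 earlier, 142 later in the 35 rDNA strain).

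With the 180 rDNA array taken 10 min earlier, so that arrays at more similar stages of S phase were compared, 414 of 2324 windows passed in limma. Of these, 223 were relatively earlier and 191 relatively later in the 35 rDNA strain. The left end of chromosome VIII from 5001 to 25000 was again first (2.11 ± 0.21, adjusted p = 0.00748), and at equal genome means its peak window was on average 24.9 points more replicated in the 35 rDNA strain. Also relatively earlier were SEC15 on chromosome VII (0.89 ± 0.08, adjusted p = 0.00723), FRE1 (chromosome XII, 570001 to 595000, 0.88 ± 0.20), PAU8 at the left end of chromosome I (0.82 ± 0.12) and FMP27 near the right end of chromosome XII (0.81 ± 0.12). Then came REF2 on chromosome IV (0.73 ± 0.14), RBH2 on chromosome X (0.72 ± 0.15), RFX1 (0.70 ± 0.13), the arsenic resistance genes ARR1, ARR2 and ARR3 on chromosome XVI (0.69 ± 0.09) and MAS1 beside the rDNA (0.69 ± 0.07). The RBH2 window holds only 5 probes, the fewest allowed.

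Relatively later at 10 min apart were windows at CWH43 on chromosome III (-0.84 ± 0.13), at RPP0 and FKS1 on chromosome XII (-0.76 ± 0.06, adjusted p = 0.00723), at SKI8 on chromosome VII (-0.69 ± 0.07), at COS12 on the left end of chromosome VII (-0.67 ± 0.14), at UGP1 on chromosome XI (-0.60 ± 0.08), at RPS11A on chromosome IV (-0.59 ± 0.09), at ERG9 on chromosome VIII (-0.58 ± 0.10) and at KCC4 on chromosome III (-0.58 ± 0.12). The windows of MET17 (-1.24 ± 0.31) and FOB1 (-0.75 ± 0.17) also passed, but hold probes that had lost their signal. Without these probes the differences were -0.35 and -0.59. At equal times the FOB1 window had a difference of 0.42, in the other direction. The count fell to 0 with slide as a random block, with centring alone and without the pair of the 45 min array of the 35 rDNA strain, and unadjusted p under 0.05 was then met by 439, 508 and 480 windows. Since no slide holds both strains, the fit with slide as a random block cannot separate strain from slide. Without the other pairs in turn it was 110, 132 and 604.

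The regions next to the rDNA were examined because the repeats and their neighbours share chromosome XII. Windows on both sides of the rDNA had higher values in the 35 rDNA strain, without passing as lists. The sign was the same under each of 42 alternatives, although the fits without 1 array repeat those without its pair. The 10 windows to the left were shifted by 0.36 ± 0.07 (SD over 4 times) against all windows at equal times (permutation p over rotations 0.0611, adjusted 0.379), and the 10 to the right by 0.34 ± 0.36 (permutation p 0.0762, adjusted 0.394). On the right the shift was 0.52 without the 30 min pair, 0.17 without the 40 min pair and 0.11 with slide as a random block (adjusted permutation p 0.160, 0.766 and 0.875). At 10 min apart, the shifts were 0.31 and 0.38 (permutation p 0.0293 and 0.00861, both 0.227 after adjustment). At equal genome means, the left and right windows were shifted by 5.92 and 7.20 points against all windows (adjusted permutation p 0.102 and 0.0734). Against matched lists, which did not keep the clustering, the adjusted permutation p at equal times was 0.0583 on the left and 0.0221 on the right. Of the 10 windows on the left, 5 were relatively earlier at 10 min apart over all windows (6 adjusted over the list alone), and of the 10 on the right 7 were (9 adjusted over the list alone), among them those of MAS1 and RFX1. None of the 20 was relatively later. At equal times 0 of them passed in limma over all windows, and 5 and 4 did when adjusted over the list alone. Chromosome XII as a whole held 48 relatively earlier and 11 relatively later windows of 202 at 10 min apart (55 and 15 adjusted over the list alone), with a shift of 0.12 at equal times that did not pass (adjusted permutation p 0.474). It passed under 3 of 42 alternatives, which were the loess profile (0.16, adjusted permutation p 0.0135), the 180 rDNA array taken 5 min earlier (0.12, adjusted permutation p 0.00667) and the deposited percentages (1.95, adjusted permutation p 0.0454). The deposited percentages were centred and scaled per array too, so 1.95 is not in percentage points. The rest of its right arm was shifted by 0.13 (adjusted permutation p 0.507), by 0.07 to 0.19 with 1 pair or array left out and by 0.05 at 10 min apart.

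**Figure D2:**
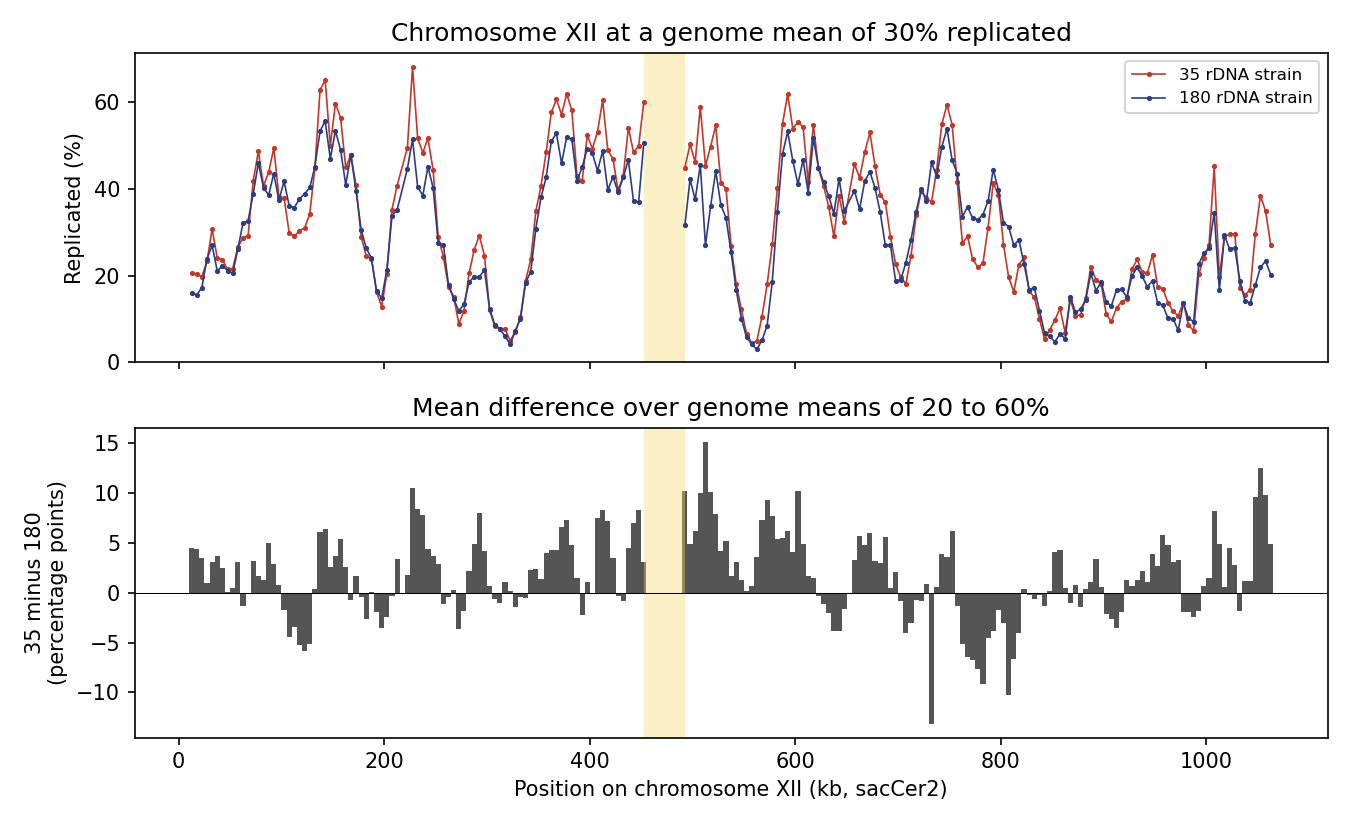
Percent replicated of 5 kb windows along chromosome XII (kb, sacCer2) at a genome mean of 30%, and the mean difference between the strains in percentage points over genome means of 20 to 60%, with the gap between windows that holds the rDNA shaded. The window of RFX1 right of the rDNA is 15.1 points higher in the 35 rDNA strain, while the window of MET17 (-13.1 points), which holds lost probes, and that of RPP0 (-10.3 points) lie below 0.

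Among the gene groups, only windows with ribosomal protein genes passed as a list at equal times. These 127 windows, which hold 138 genes chosen by symbol prefix, were relatively later in the 35 rDNA strain by a shift of -0.15 ± 0.12 (SD over 4 times), with the same sign at 4 of 4 times (permutation p 0.00043, the smallest that the rotations can give, adjusted 0.0133). The prefix also brings in RPP1, a gene for a ribonuclease subunit, and without it, a choice made after the data were seen, the shift was -0.15 (adjusted permutation p 0.0133). Against matched lists the adjusted permutation p was 0.0365. At equal genome means the shift was -1.22 points (adjusted permutation p 0.0133). The comparison at equal genome means pairs no times and does not use the 30 min array of the 35 rDNA strain. At equal times the result rested on the 30 min pair, without which the shift was -0.05 with an adjusted permutation p of 0.461. With normexp the sign turned to 0.03. The list also no longer passed with quantile normalization, loess within arrays or the loess profile (adjusted permutation p 0.0667, 0.145 and 0.0785). Nor did it pass with 35 rDNA arrays paired with arrays of the other strain taken 5 min later (adjusted permutation p 0.109). It passed under 27 of 43 alternatives, in which fits without 1 array repeat those without its pair. At 10 min apart the shift was -0.06 (adjusted permutation p 0.227), and the members went both ways. Of the 127 windows 17 were relatively later and 11 relatively earlier (24 and 14 adjusted over the list alone). Those of RPP0 (-0.76), RPS11A (-0.59), RPL38 (-0.55) and RPS26A (-0.53) were relatively later, and those of RPS11B (0.58), RPS21B (0.48), RPL23A (0.45) and RPL37A (0.40) relatively earlier. At equal times 0 of the 127 passed in limma, also when adjusted over the list alone, for example RPL23A at 0.88 with an unadjusted p of 0.00396.

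The other gene groups and regions did not pass at equal times with the choices used throughout, and some passed under other choices. With centring alone, windows near centromeres (0.35), with histone genes (0.71), with tRNA genes (0.11) and with PAU genes (0.32) did, at adjusted permutation p of 0.0200, 0.0240, 0.0200 and 0.0240. With normexp those with histone genes (0.72) and tRNA genes (0.13) did, at 0.0467 and 0.0133. Windows with PAU genes, a subtelomeric family of cell wall proteins, were shifted by 0.21 (adjusted permutation p 0.320), but by -0.07 with normexp and by -0.44 with loess within arrays, which passed in the other direction (adjusted permutation p 0.0133). The list passed under 9 of 42 alternatives, among them also 10 kb windows (0.31, adjusted permutation p 0.0130), the loess profile (0.26, adjusted permutation p 0.0359) and the fit without the 40 min pair (0.32, adjusted permutation p 0.0400). The fits without 1 array of the 40 min pair repeat the last of these and are counted among the 9. The shift was 0.09 at 10 min apart. Of the 19 windows 0 passed at equal times in limma (2 adjusted over the list alone). At 10 min apart 4 were relatively earlier, including PAU13 and PAU8, and 2 relatively later, PAU5 and PAU20 (5 and 2 adjusted over the list alone). Windows with histone genes were shifted by 0.43 ± 0.54 (SD over 4 times, adjusted permutation p 0.320), or 0.21 without the 30 min pair and 0.01 at 10 min apart (permutation p 0.954, same sign in 2 of 4 pairs), with values from 0.85 at HTB1 to -0.36 at HHT2 and HHF2, and HHT2 was relatively later at 10 min apart (-0.32 ± 0.08, adjusted p = 0.0366 in limma). Windows with COS genes were shifted by 0.24 (adjusted permutation p 0.507), but by -0.08 with loess within arrays. The shift was 0.12 without the 40 min pair and 0.15 without the 35 min pair. This list, chosen by symbol prefix, has its median at the window of COS111 on chromosome II, which is not subtelomeric, and without this gene, likewise chosen afterwards, the shift was 0.19 (adjusted permutation p 0.704). Of its members, COS8 was relatively earlier and COS12 relatively later at 10 min apart. The shift was 0.04 near centromeres (adjusted permutation p 0.761), but -0.05 with quantile normalization. The centromere list kept its direction under 30 of 44 alternatives and passed under 3, not all of them in this direction. Near chromosome ends the shift was 0.07 (adjusted permutation p 0.507), but -0.05 with centring alone. For these the adjusted permutation p against matched lists was 0.0139 and 0.0263. For the centromeres the matched lists lay higher than the list itself. Near the ends 0 of 172 windows passed over all windows and 13 did when adjusted over the list alone. tRNA genes had 0.03, Ty gag-pol genes 0.06, origin firing factor genes 0.13, rDNA and mitotic exit genes 0.14, replication licensing genes 0.05 and the silent mating loci -0.19, with adjusted permutation p from 0.748 to 0.761. Of these, the signs of the Ty gag-pol, origin firing factor, replication licensing and silent mating lists turned under loess within arrays (-0.28 for Ty gag-pol genes) or normexp (0.39 for the silent mating loci). The rDNA and mitotic exit list turned to -0.27 at 10 min apart (permutation p 0.0280, adjusted 0.227) and to -0.26 with the 180 rDNA array 5 min earlier, and kept its direction under 30 of 42 alternatives. The tRNA list turned to -0.03 with 2 kb windows. Among single chromosomes the shifts at equal times ran from -0.16 on chromosome XI (permutation p 0.0473, adjusted 0.367) to 0.12 on chromosome XII, and 0 of 16 passed with rotations.

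**Figure D3:**
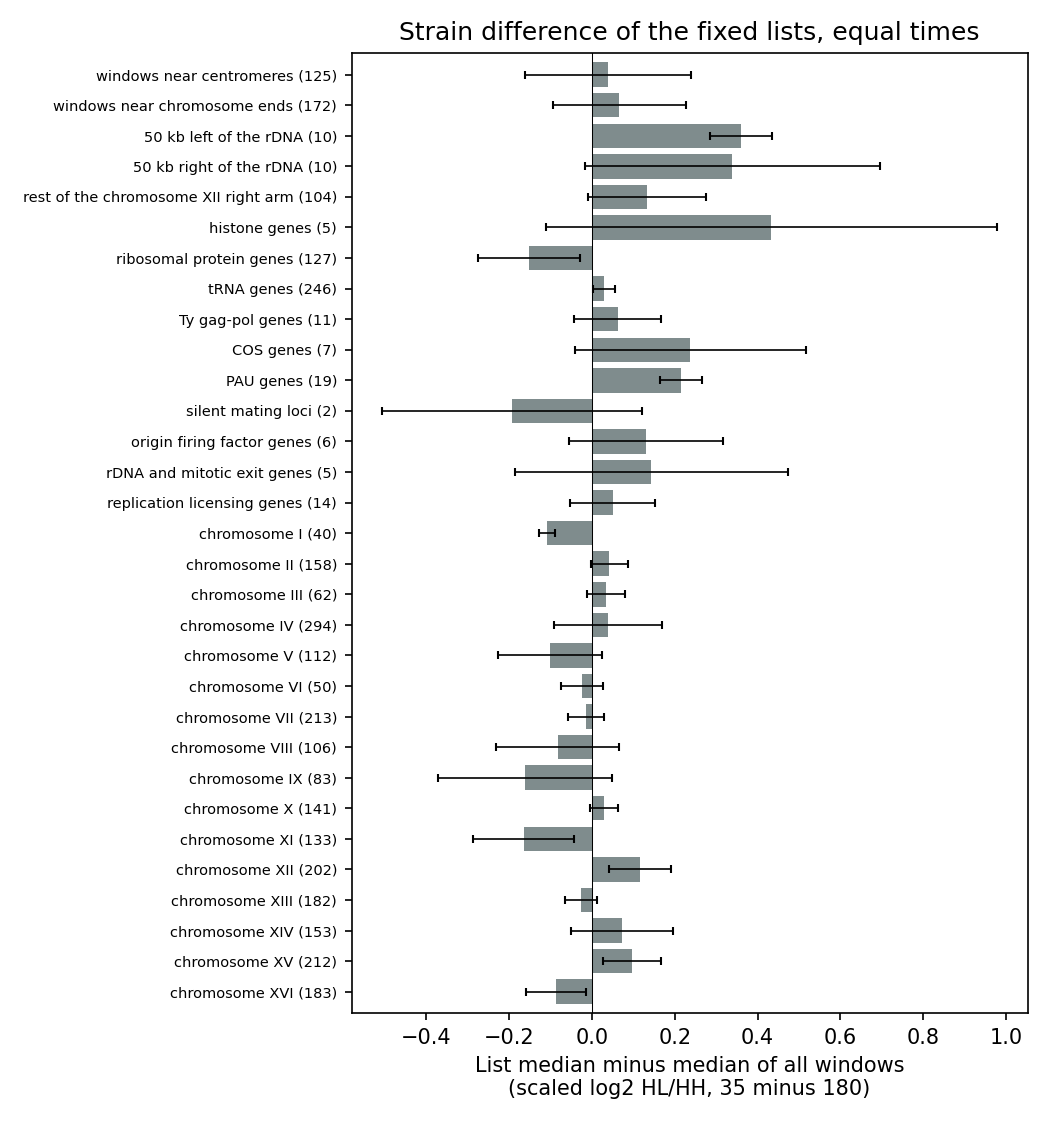
Shift of each fixed list against all windows at equal times (bars, scaled log2 HL/HH, 35 rDNA minus 180 rDNA strain) with the SD over the 4 shared times and the number of windows in brackets. Ribosomal protein genes (-0.15, but 0.03 with normexp) passed the rotations, and the windows left and right of the rDNA (0.36 and 0.34) did not.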

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

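Tests of a lag of the whole culture, of the place of the ribosomal protein windows in S phase, of the rDNA without the probe with a saturated spot, and all comparisons with arrays 10 min apart were chosen after the result was seen.

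The rDNA spacer probes differed between the strains in relative log2 of HL over HH by 1.87, ahead of the genome in 1 strain and behind it in the other. A bias of bright probes is argued against by the 100 brightest other nuclear probes, whose median difference was 0.19 (5% to 95% range -0.63 to 1.15), although their signal was below that of the rDNA. Saturation as the cause needed at least 1 saturated rDNA spot and 1 of 44 was found, but without that probe the difference was 1.76 (exact permutation p = 0.0108, 3 probes left). A lag of the whole culture would leave no difference at equal genome means. At 30% the difference was 39.0 points, against an SD over probes of 4.32. That SD is a spread over 4 probes of the same arrays, not between cultures or slides. The rDNA copy number stays a candidate explanation, which the design confounds with slide, scan and Feature Extraction protocol. It is also confounded with other differences between the strains, such as the signal of LEU2 and MET17 lost in the 35 rDNA strain only. With normexp the difference in relative log2 of HL over HH was 1.10 without passing.

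The left end of chromosome VIII was relatively earlier in the 35 rDNA strain by 1.36 as the median of 5 windows. A shift of all chromosome ends is argued against by the other 167 end windows, with a median of 0.12. Extra signal in bright probes alone is argued against by the 22 probes of ordinary brightness, with a median of 1.21 beside 1.21 for the other 50. All 22 of 22 were positive, but the region was chosen for its difference, so their sign adds no evidence. Ordinary brightness does not show that a probe matches only 1 place. Signal from other copies of subtelomeric sequence therefore stays open. A change in copies of the region stays open: the median total signal of its 72 probes differed by 0.50, which only just reaches the 0.5 set before the test, and the SD over all probes was 0.53. A difference in sequence or origin use between the strains may also underlie it and was not tested, and slide and strain cannot be told apart.

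Windows with ribosomal protein genes were relatively later in the 35 rDNA strain at equal times, by -0.15. Probes inside these genes are argued against by a shift of -0.14 without them, and a trend with probe brightness by a shift of -0.14 after its removal, both at the smallest permutation p that rotations can give (0.00043). Their place in S phase is argued against by a permutation p of 0.0106 among matched lists. The sign turned with normexp (0.03), and without the 30 min pair the shift was -0.05. The list also no longer passed with quantile normalization, loess within arrays or the loess profile. Nor did it pass with 35 rDNA arrays paired with arrays of the other strain taken 5 min later or 10 min earlier. Background correction, normalization, smoothing, the pairing of times and 1 pair of arrays may therefore account for the result at equal times. At equal genome means the shift was -1.22 points (adjusted permutation p 0.0133), with the same sign at 5 of 5 levels, which share arrays. That comparison was chosen after the data were seen. It pairs no times and does not use the 30 min array of the 35 rDNA strain, but background correction and normalization were not varied in it. The rDNA copy number as a biological explanation was not tested, and strain and slide cannot be told apart.

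At equal times 0 windows passed in the real split of the 8 arrays (521 at an unadjusted p under 0.05 in limma), and at most 0 in the other splits that part all 4 pairs. Beside a count of 0 all 8 of 8 splits give as many whatever the data, so this tells nothing. At 10 min apart 414 passed in the real split and at most 0 in the others, so 1 of 8 did. These 8 splits are too few for a share under 0.05. Splits that part only some pairs, of which 24 were fitted and 3 could not be fitted, gave up to 360 windows at equal times and up to 15 at 10 min apart. With arrays listed pair by pair and the 35 rDNA strain first, the 360 (splits 20 and 25) and the 15 (splits 2 and 7) come from splits that part 2 pairs by strain, and so also by slide. The 360 rest on the 30 and 35 min pairs, whereas all 4 pairs gave 0. They point to a structure of the samples, and a difference between strains or slides that varies with time is not excluded.

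The array of the 180 rDNA strain at 25 min stood apart with a derivative log ratio SD of 0.368 (others 0.214 to 0.259), with 4122 probes not well above background (others 60 to 534) and with 4 saturated probes (others 0 to 1). In the 35 rDNA strain, the 50 min array had 72 probes not well above background (others 33 to 40) and an rDNA HH level of 4.37 (others 3.45 to 3.57). The 40 min array had 1 saturated probe (others 0). Of 32 groups tested, 6 held such an array. For independent values chance gives about 1 in 20, but this rate does not apply here, because the arrays are successive times of S phase. A count of 1 beside counts of 0 is also marked in any case.

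The 295 mitochondrial probes, which enter no comparison, had a total signal over the nuclear median of 3.31 ± 0.38 (SD, n = 5) in the 35 rDNA strain and -0.43 ± 0.68 (SD, n = 6) in the 180 rDNA strain, a difference of 3.75 (exact permutation p = 0.00216, the smallest that 462 splits can give). On the 35 rDNA arrays 3 to 112 of these probes were saturated and on the 180 rDNA arrays 0, so its size is affected. Over the 182 probes saturated on no array, a test chosen after the data were seen, the difference was 4.09 at the same smallest exact permutation p. Both tests take successive times of 1 course per strain as independent arrays.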

How the results depend on the processing

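Arrays 10 min apart, equal genome means, gene positions moved by 500 bp, lists without RPP1 and COS111, probes that lost their signal, the 5S probe, the copy estimate, the rDNA relative replication, the probe minimum for peaks and the fixed 40% level were chosen after the data were seen. So was leaving each array out of the comparison of the rDNA signal. The other alternatives were set before the data were examined. The rDNA relative replication kept its direction under each of 15 alternatives and its side of the threshold under 14, and was 1.10 with normexp. The windows left and right of the rDNA kept their sign under each of 42 alternatives and passed under 0. Of 1432 values of named windows, 1203 kept direction and side of the threshold, 207 came to pass it and 22 reversed. Of 1304 values of lists, 1102 stayed, 20 came to pass, 15 no longer passed and 167 reversed. These counts of windows and lists hold repeats, because each fit at equal times without 1 array repeats the fit without its pair. For all that follows the cause was not tested, apart from fewer arrays in the fits that leave some out.

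The rDNA signal averaged over both channels (-0.28) was 0.51 with normexp, -1.20 in HH alone and 0.65 in HL alone. It was -0.97 without the 5S probe, and the copy estimate was -0.82, or -1.50 without the 5S probe. The mean profile correlation was 0.953 with arrays 10 min apart. At a smoothing span of 10 kb there were 731 and 802 peaks, 664 of them shared. The median delay was 8.69 min at the fixed level of 40%.

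Against 0 windows at equal times (521 at an unadjusted p under 0.05 in limma), the number passing, with those relatively earlier and later in the 35 rDNA strain in brackets, moved with several settings. It was 3 with quantile normalization (3 and 0), 40 with loess within arrays (21 and 19), 2 with only probes well above background (2 and 0) and 3 with 10 kb windows (3 and 0). Other settings gave 91 with the loess profile (79 and 12), 423 with a quadratic in time over all 11 arrays (281 and 142), 33 with the 180 rDNA array 5 min earlier (31 and 2) and 414 with arrays 10 min apart (223 and 191). Then came 432 with arrays 10 min apart without probes that lost their signal (232 and 200), 462 with arrays 10 min apart and percentiles (252 and 210), 110 with arrays 10 min apart without the pair of the 35 min array of the 35 rDNA strain (75 and 35) and 132 with arrays 10 min apart without the pair of the 40 min array of the 35 rDNA strain (64 and 68). The last gave 604 with arrays 10 min apart without the pair of the 50 min array of the 35 rDNA strain (311 and 293). Leaving out 1 pair or array gave 0 to 3 windows, and 3 passed only where the 30 min pair or 1 of its arrays was left out. It was 0 for the other settings at equal times and for arrays 10 min apart with slide as a random block, with centring alone and without the pair of the 45 min array of the 35 rDNA strain.

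The shift of a list changed sign or side of the threshold, and the difference of a named window changed sign, as follows, in scaled log2 units where no other is named. The 207 window values that came to pass are given only as a count. A list value with the sign it has at equal times is one that came to pass, or, for ribosomal protein genes, no longer passed. With centring alone, it was 0.35 for centromeres, -0.050 for chromosome ends, 0.71 for histone genes and 0.11 for tRNA genes. It was 0.32 for PAU genes, -0.025 for replication licensing genes, 6.6e-05 for chromosome VI and 0.0067 for chromosome XIII. This setting also gave 0.015 for the window at 80001 of chromosome III. With percentiles (in percentile points), it was -0.84 for centromeres, -0.60 for replication licensing genes, 0.15 for chromosome VII and 0.53 for chromosome XIII. With quantile normalization, it was -0.048 for centromeres, -0.11 for ribosomal protein genes, -0.017 for replication licensing genes and 0.00022 for chromosome VII. Further values were -0.00017 for chromosome X and 0.014 for chromosome XIII. With normexp, it was -0.099 for chromosome ends, 0.029 for ribosomal protein genes, 0.72 for histone genes and 0.13 for tRNA genes. The shift was also -0.071 for PAU genes, 0.39 for silent mating loci, -0.027 for origin firing factor genes and -0.015 for replication licensing genes. Other values were 0.017 for chromosome VII, -0.017 for chromosome X, -0.037 for chromosome XIV and 0.10 for the window at 1 of chromosome VII. The same setting gave 0.31 for the window at 490001 of chromosome IV.

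With loess within arrays, it was -0.14 for chromosome ends, -0.078 for ribosomal protein genes, -0.28 for Ty gag-pol genes and -0.076 for COS genes. It was -0.44 for PAU genes, 0.023 for silent mating loci, -0.043 for replication licensing genes and 0.020 for chromosome VII. This setting also gave 0.022 for chromosome XIII, -0.053 for chromosome XIV and -0.20 for the window at 1 of chromosome I. With only probes well above background, it was -0.0052 for rDNA and mitotic exit genes. With 2 kb windows, it was -0.029 for tRNA genes and 0.35 for silent mating loci. With 10 kb windows, it was -0.034 for Ty gag-pol genes, 0.31 for PAU genes, 0.22 for silent mating loci and 2.4e-05 for chromosome XIII. With the loess profile, it was -0.093 for ribosomal protein genes, 0.26 for PAU genes, 0.46 for silent mating loci and 0.029 for chromosome VI. Further values were 0.016 for chromosome VII, 0.16 for chromosome XII and 0.031 for the window at 730001 of chromosome XII. With a quadratic in time over all 11 arrays, it was -0.059 for replication licensing genes. With the 180 rDNA array 5 min earlier, it was -0.26 for rDNA and mitotic exit genes, -0.032 for replication licensing genes, 0.12 for chromosome XII and 0.016 for chromosome XIII. The shift was also -0.23 for the window at 675001 of chromosome IV. With the 180 rDNA array 5 min later, it was 0.13 for chromosome ends, -0.074 for ribosomal protein genes, 0.54 for histone genes and 0.40 for PAU genes. Other values were -0.070 for replication licensing genes, 0.076 for chromosome I, 0.036 for chromosome VI and 0.0091 for chromosome XIII.

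With arrays 10 min apart, it was -0.013 for centromeres, -0.065 for ribosomal protein genes, -0.0015 for tRNA genes and 0.091 for silent mating loci. The same setting gave -0.27 for rDNA and mitotic exit genes, -0.029 for replication licensing genes, -0.0021 for chromosome II and -0.023 for chromosome IV. It was 0.069 for chromosome XIII, -0.030 for chromosome XIV and -0.75 for the window at 675001 of chromosome IV. The deposited percentages were centred and scaled per array too, so their values are not percentage points. With them, it was 4.89 for centromeres, 17.36 for histone genes, 3.77 for PAU genes and 0.31 for chromosome VI. This setting also gave 1.95 for chromosome XII and 1.13 for the window at 1 of chromosome VII. Without windows near chromosome ends, it was -0.065 for chromosome III. Without probes that lost their signal, with arrays 10 min apart, it was -0.0078 for centromeres, -0.071 for ribosomal protein genes, -0.0030 for tRNA genes and 0.085 for silent mating loci. Further values were -0.28 for rDNA and mitotic exit genes, -0.035 for replication licensing genes, -0.026 for chromosome IV and 0.061 for chromosome XIII. The shift was also -0.036 for chromosome XIV and -0.59 for the window at 675001 of chromosome IV. Using slide as a random block with arrays 10 min apart, it was -0.026 for centromeres, -0.056 for ribosomal protein genes, -0.040 for histone genes and -0.0023 for tRNA genes. Other values were -0.038 for Ty gag-pol genes, 0.0069 for silent mating loci, -0.27 for rDNA and mitotic exit genes and -0.031 for replication licensing genes. The same setting gave -0.034 for chromosome IV, 0.0030 for chromosome VII, 0.060 for chromosome XIII and -0.031 for chromosome XIV. It was -0.83 for the window at 675001 of chromosome IV. Using centring alone with arrays 10 min apart, it was -0.22 for centromeres, -0.22 for histone genes, -0.058 for tRNA genes and -0.11 for Ty gag-pol genes. This setting also gave 0.24 for silent mating loci, -0.031 for origin firing factor genes, -0.13 for rDNA and mitotic exit genes and -0.0080 for replication licensing genes. Further values were -0.048 for chromosome III, 0.0054 for chromosome VII, -0.029 for chromosome X and 0.012 for chromosome XIII. The shift was also 0.026 for chromosome XVI and -0.46 for the window at 675001 of chromosome IV.

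Using percentiles (in percentile points) with arrays 10 min apart, it was -0.24 for centromeres, -2.03 for ribosomal protein genes, 2.47 for silent mating loci and -5.15 for rDNA and mitotic exit genes. Other values were -1.08 for replication licensing genes, -0.13 for chromosome II, -0.49 for chromosome IV and 0.022 for chromosome VII. The same setting gave 1.52 for chromosome XIII, -1.02 for chromosome XIV, -2.90 for the window at 305001 of chromosome III and -9.10 for the window at 675001 of chromosome IV. Without the pair of the 35 min array of the 35 rDNA strain, with arrays 10 min apart, it was -0.016 for centromeres, -0.051 for ribosomal protein genes, -0.021 for histone genes and -0.012 for tRNA genes. It was 0.081 for silent mating loci, -0.20 for rDNA and mitotic exit genes, -0.042 for replication licensing genes and -0.00065 for chromosome II. This setting also gave -0.0084 for chromosome III, -0.030 for chromosome IV, 0.062 for chromosome XIII and -0.027 for chromosome XIV. Further values were -0.67 for the window at 675001 of chromosome IV. Without the pair of the 40 min array of the 35 rDNA strain, with arrays 10 min apart, it was -0.045 for centromeres, -0.056 for ribosomal protein genes, -0.090 for histone genes and -0.010 for tRNA genes. The shift was also -0.064 for Ty gag-pol genes, -0.36 for rDNA and mitotic exit genes, -0.027 for replication licensing genes and -0.0063 for chromosome III. Other values were -0.030 for chromosome IV, 0.050 for chromosome XIII, -0.017 for chromosome XIV and -0.83 for the window at 675001 of chromosome IV. Without the pair of the 45 min array of the 35 rDNA strain, with arrays 10 min apart, it was -0.012 for centromeres, -0.038 for ribosomal protein genes, -0.031 for Ty gag-pol genes and 0.036 for silent mating loci. The same setting gave -0.20 for rDNA and mitotic exit genes, -0.012 for replication licensing genes, -0.020 for chromosome II and -0.029 for chromosome IV. It was 0.010 for chromosome VII, 0.057 for chromosome XIII, -0.037 for chromosome XIV and 0.0094 for chromosome XVI. This setting also gave -0.097 for the window at 305001 of chromosome III and -0.80 for the window at 675001 of chromosome IV. Without the pair of the 50 min array of the 35 rDNA strain, with arrays 10 min apart, it was -0.0019 for chromosome ends, -0.067 for ribosomal protein genes, 0.32 for silent mating loci and -0.26 for rDNA and mitotic exit genes. Further values were -0.051 for replication licensing genes, 0.027 for chromosome VII, 0.060 for chromosome XIII and -0.032 for chromosome XIV. The shift was also -0.62 for the window at 675001 of chromosome IV. With a radius of 40 kb, it was -0.11 for centromeres. With equal genome means (in points), it was 1.72 for silent mating loci, -3.58 for rDNA and mitotic exit genes, -0.38 for replication licensing genes and -0.089 for chromosome IV. Other values were 0.68 for chromosome XIII and -0.63 for chromosome XIV. With slide as a random block, it was 0.14 for the window at 1 of chromosome VII.

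Leaving out 1 pair or array at equal times, the values ranged as follows: -0.024 to 0.097 for centromeres, 0.017 to 0.15 for chromosome ends, 0.31 to 0.41 for 50 kb left of the rDNA, 0.17 to 0.57 for 50 kb right of the rDNA, -0.22 to -0.053 for ribosomal protein genes, 0.067 to 0.19 for the rest of the XII right arm and 0.21 to 0.58 for histone genes. For further lists they ranged from 0.024 to 0.039 for tRNA genes, 0.019 to 0.079 for Ty gag-pol genes, 0.11 to 0.37 for COS genes, 0.15 to 0.34 for PAU genes, -0.30 to -0.058 for silent mating loci, 0.040 to 0.22 for origin firing factor genes and 0.044 to 0.15 for rDNA and mitotic exit genes. For the others they ranged from -0.15 to 0.061 for replication licensing genes, -0.056 to 0.020 for chromosome VI, -0.036 to 0.0061 for chromosome VII, -0.0023 to 0.044 for chromosome X, -0.038 to 0.024 for chromosome XIII and -0.43 to 0.11 for the window at 1 of chromosome VII. The ribosomal protein list no longer passed without the 30 min pair or 1 of its arrays (adjusted permutation p 0.461). Signal over background limits the 25 min array of the 180 rDNA strain most, with 4122 nuclear probes not well above it, and this array enters the comparison 10 min apart and not the one at equal times.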

Other observations

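Among genes that act at the rDNA and in mitotic exit, the 10 min comparison, chosen after the data were seen, moved single members in both directions. The window of NET1, which encodes a nucleolar protein that holds the phosphatase Cdc14, was relatively earlier in the 35 rDNA strain (0.57 ± 0.09, adjusted p = 0.0199 in limma), and at equal genome means it was 7.57 ± 1.25 points more replicated (SD over 5 levels). With slide as a random block, with centring alone or without the pair of the 45 min array of the 35 rDNA strain, 0 of all windows passed in limma at 10 min apart (439, 508 and 480 at an unadjusted p under 0.05), so neither this nor any window below did. The window of CDC14 itself was relatively later (-0.37 ± 0.08, adjusted p = 0.0243). So was that of FOB1 (-0.75 ± 0.17, adjusted p = 0.0303), but it holds probes that had lost their signal. Of the 5 windows 1 was thus relatively earlier and 2 relatively later, and SIR2 (-0.27) and TOF2 (0.05) did not pass.

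Of the 14 windows with replication licensing genes, 3 were relatively earlier in the 35 rDNA strain at 10 min apart, and 0 relatively later, with adjusted p from 0.0280 to 0.0477 in limma and with the same loss under those 3 settings. Of all 2324 windows, 223 were relatively earlier and 191 relatively later. The list as a whole was shifted by -0.03 at 10 min apart (permutation p over rotations 0.673), so the members give no shift of the group. The 3 windows that passed hold ORC3 (0.35 ± 0.08), ORC5 (0.32 ± 0.09) and ORC1 (0.25 ± 0.07), which encode subunits of the origin recognition complex. The other subunit genes of the complex, ORC2 (-0.11), ORC4 (-0.03) and ORC6 (-0.14), did not pass. The windows of the helicase subunit genes MCM2 to MCM7 did not pass, with values from -0.14 at MCM6 to 0.09 at MCM3. Among origin firing factor genes, DPB11 had 0.33 ± 0.16 and SLD2 -0.17 ± 0.08 at 10 min apart, which did not pass.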
